A study of Mus musculus with 6 samples.

How the data were processed

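Total RNA of embryonic kidneys was extracted with a column kit, checked on a Bioanalyzer, amplified to biotinylated cRNA and hybridised to Illumina bead arrays, per the labels' protocols. The deposited values used here are log2 signals of 45281 probes on 6 arrays, and the deposited value table holds 1 column per sample. The sorted values of the 6 columns differed by at most 0.00608 on the log2 scale, which is what quantile normalization leaves; the software and the background step behind these log2 values are not given in the sources used here. No value lies near 0 and the median is 7.30 on each array, so no background subtraction is visible, and folds understate the change of dim probes.

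A second deposited table, of values before normalization, was not used here. Its 12 columns of per-sample values, 6 of signal and 6 of detection p, carry names that match no sample's labels, and columns were not matched by order or by values. The planned analysis, which started from that table with neqc and a filter on detection p, was therefore replaced by its stated fallback: limma on the deposited log2 values, testing the 50% of probes with the highest mean over all 6 arrays (a mean log2 above 7.29).

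Probes were named through the platform annotation, which pairs probes with gene symbols and can be old. Of the probes, 34885 had 1 gene symbol, 18 had several and were not named, and 10378 were not listed. Gene identifiers of 34807 probes matched the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols; that table was used for names and for which genes neighbour each other, and no coordinates are given because the sources name no build. Each probe was tested by itself. For gene lists and for genes named from them, the tested probe with the highest mean stood for the gene, and for a gene named in the report the other tested probes are given where 1 of them differs in sign; a further probe of the same sign can be smaller in size and is not always given.

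The comparison of 3 YapCM-/- with 3 control arrays was a 2-group fit with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without covariates, trend or robust options. P-values were adjusted by the Benjamini-Hochberg method over the 22640 tested probes, with a threshold of 0.05, and every adjusted p of a gene is from this fit. The 25 gene lists were compared with other genes by camera of limma with an inter-gene correlation of 0.01, adjusted over the 22 lists that had at least 5 tested members, without the sex-linked list. The lists were also tested with a correlation estimated from the data and with fry. With an estimated correlation, camera rests on the few residual degrees of freedom of the arrays. That alone raises its p, so a call lost there need not come from correlation among the genes. The main test of fry asks whether the members of a list move on balance 1 way. Its mixed test asks for changes in either direction, without comparing the list with other genes. The median log2 difference of all tested genes was 0.0039. The lists come from textbook knowledge of kidney development and of Hippo signalling.

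The groups, the tests, the gene lists, the other settings and the rule for named genes were set before the data were examined. The rule takes Yap1, then the 10 genes with the largest rise and the 10 with the largest fall among probes past the threshold whose groups do not overlap, with 1 probe per gene and without predicted genes that have no symbol of their own. From each list it takes up to 4 members past the threshold, or the 2 with the smallest p if none passed. Genes outside the rule are said to have been named after their values were seen.

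The fit was tested on simulated data made from the means and moderated SDs of the tested probes, with 200 probes changed in each of 10 runs. The moderated SDs of eBayes are drawn towards a common value, so the recovered shares may be too favourable for the real data. The fit recovered 79.7% of the probes changed by 0.5 on the log2 scale, 99.7% of those changed by 1 and 100% of those changed by 1.5. Of its calls 6.66% were false. In simulated data without list effects 0 of 220 list tests passed, and a list of 17 genes shifted by -0.2 passed in 10 of 10 runs; the simulated probes vary independently, unlike real ones. Other settings covered the filter on dim probes, the eBayes options, array weights, the replicate number as a block, the threshold, the mean of a gene's probes, each array left out in turn, background subtraction, another normalization and the Xist signal as a covariate, the last 3 and a stricter filter added later. The number of arrays, 3 per group, limits the precision of every value.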

Results

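Gene expression was measured in whole embryonic kidneys of the mouse at E13.5, in mid-gestation, with total RNA amplified, labelled with biotin and hybridised to Illumina bead arrays. The 6 arrays fell into 2 groups, 3 of control kidneys and 3 of kidneys named YapCM-/-, all on a mixed C57BL/6 and 129S1/SvImJ background. The comparison asked which transcripts differ when Yap, the transcriptional coactivator held in check by Hippo signalling, is lost; the labels do not spell out CM, and from what is known of the study it stands for the cap mesenchyme, the nephron progenitors around the ureteric bud tips. Values are log2 signals that were already quantile normalized, with a median of 7.30 on each array, and carry no visible background subtraction, so that the folds given here understate the change of dim probes. The correlation across tested probes, which are not independent replicates, lay between 0.983 and 0.993 for the 15 pairs of arrays. On the first principal component, which held 35.3% of the variance, control replicate 2 lay farthest from the other arrays, at -23.0. The number of arrays, 3 per group, limits the precision of each value. The labels do not say whether the replicates came from separate embryos or litters. Xist was high on 1 array of each group, so the arrays of a group did not all come from 1 RNA sample. The p-values measure the spread between these samples, which may in part be technical.

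Yap1 itself fell in the YapCM-/- kidneys. Its 1 probe read 9.73 ± 0.09 (SD, n = 3) in control and 8.87 ± 0.14 (SD, n = 3) in YapCM-/- kidneys, a log2 difference of -0.86 (SE 0.093, limma adjusted p = 0.0102), with all 3 mutant arrays below all 3 control arrays. The control level was 1.81-fold the mutant level, so transcript remained in the mutant organ. Whether the probe lies in the deleted part of the gene is not given in the sources used here. The call was lost without control replicate 1 (adjusted p = 0.0954) and without control replicate 3 (adjusted p = 0.0518), and with the background subtracted (log2 difference -1.08, adjusted p = 0.178).

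Across the organ, the transcripts that fell most included those of nephron progenitors and of the proximal tubule, and those that rose included Ret and Fgf10, a receptor and a growth factor with roles in ureteric bud growth. The largest fall belonged to Spink1, a secreted trypsin inhibitor, at -1.27 (SE 0.101, adjusted p = 0.00175), from 9.19 ± 0.19 to 7.93 ± 0.06 (SD, n = 3 each). Meox2, a homeobox gene of the cap mesenchyme, fell by 1.09 on the log2 scale (SE 0.092, adjusted p = 0.00175), and Sostdc1, a secreted antagonist of BMP and Wnt signals, by a log2 difference of -0.97 (SE 0.120, adjusted p = 0.0183). Meox2 and Sostdc1 are neighbours on their chromosome, 2 genes apart. Capn6, a calpain without protease activity, fell from 11.43 to 10.64 (log2 difference -0.79, adjusted p = 0.0178). Ret, the receptor tyrosine kinase for GDNF at the ureteric bud tips, rose by 0.83 (SE 0.095, adjusted p = 0.0147), and Fgf10, a fibroblast growth factor, by 0.65 (SE 0.089, adjusted p = 0.0313). Slc32a1, the vesicular transporter for GABA and glycine, rose by 0.98 (adjusted p = 0.00175), and Flrt1, a leucine-rich transmembrane protein, by 1.02 (adjusted p = 0.00175). Abhd16a, a lipid hydrolase, rose by 0.78 (adjusted p = 0.00662), Wdfy1 by 0.75 (adjusted p = 0.0328), Col26a1, a collagen gene, by 0.67 (adjusted p = 0.0178) and Dlgap1, a synaptic scaffold gene, by 0.63 (adjusted p = 0.0183), with its other probe at 0.24 (adjusted p = 0.488). Of the 6 fits that leave out 1 array, Fgf10 and Wdfy1 missed the threshold in 5, Dlgap1 in 4, Col26a1 in 3, Ret, Sostdc1 and Capn6 in 2, and Abhd16a in 1.

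For several genes the probes did not move together. The largest rise, 1.48 (SE 0.191, adjusted p = 0.0235), came from a dim probe of Actb, the gene of cytoplasmic beta-actin, and another dim probe rose with it (adjusted p = 0.0350), while the brightest Actb probe differed by 0.24 and did not pass (adjusted p = 0.363). Mff, a receptor for mitochondrial fission, had 1 probe that fell by 0.84 (adjusted p = 0.0328) and others at 0.28 (adjusted p = 0.426) and 0.0071 (adjusted p = 0.984). Pigt, a subunit of the GPI transamidase, had 1 probe that fell by 0.88 (adjusted p = 0.0407) and a brighter one at 0.17 (adjusted p = 0.689). The other probes of Flrt1 and Col26a1 differed by 0.05 and -0.03, and that of Ret by 0.57 (adjusted p = 0.103). The other probes of Fgf10 differed by 0.42 (adjusted p = 0.195) and 0.12 (adjusted p = 0.606). ND5, a mitochondrially encoded subunit of complex I, rose by 1.16 (SE 0.145, adjusted p = 0.0183) on its 1 probe. With 1 array left out, Mff missed the threshold in all 6 fits, Pigt and ND5 in 4 and the Actb probe at 1.48 in 3.

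**Figure D1:**
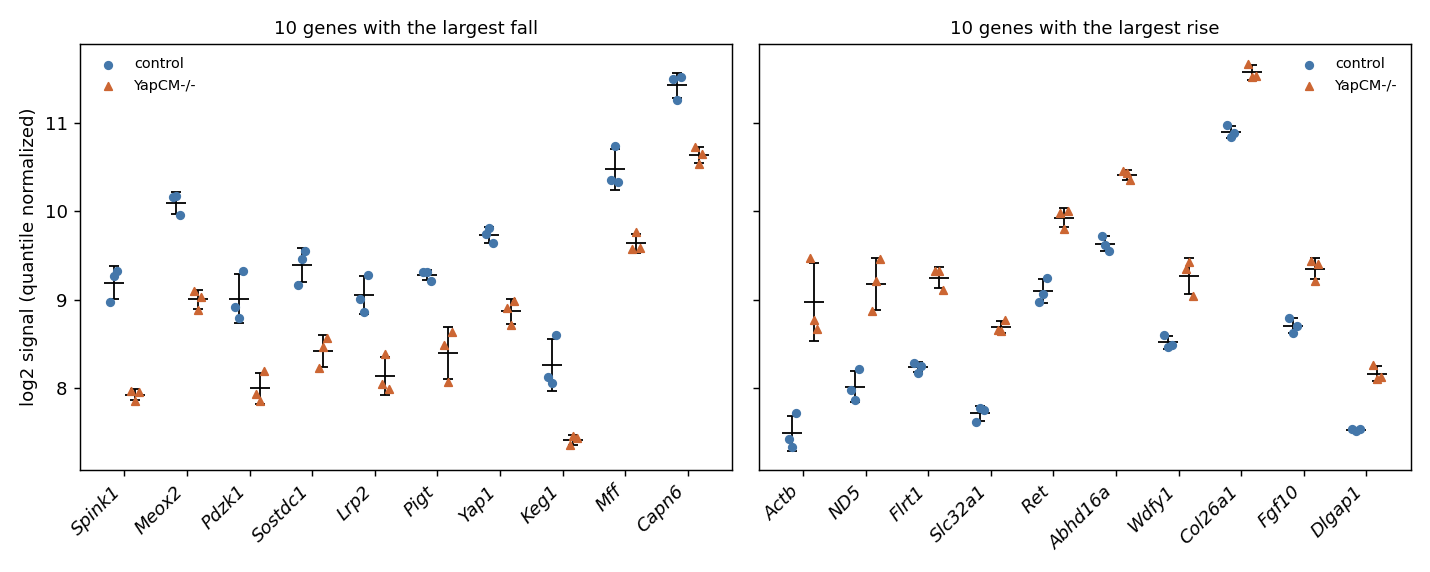
Quantile-normalized log2 signal (vertical axis) of the 10 genes with the largest fall (left) and the 10 with the largest rise (right) among probes past the threshold, with each array as a point, control as circles and YapCM-/- as triangles, and the group mean with its SD as a bar (n = 3 per group). The genes were chosen by their test and size, and range from Spink1 at a log2 difference of -1.27 to Actb at 1.48.

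In all, 22640 probes were tested, which covered 11762 named genes and included 3954 probes without 1 gene symbol. Of these probes 40 passed an adjusted p of 0.05 in limma, 17 higher and 23 lower in YapCM-/- kidneys. They covered 35 named genes, 15 higher and 20 lower, and 4 probes without 1 gene symbol. Their differences ranged from 1.42-fold to 2.83-fold, and 28 of them reached 1.5-fold. The groups did not overlap at any of the 40 probes, nor at 16.5% of all tested probes, against the 10% that chance gives for 3 against 3. At an unadjusted p under 0.05 stood 2594 probes, 1253 of them higher, where chance alone would give 1132 on average. Other splits of the arrays into 3 and 3 gave from 506 to 1881 such probes. The count of 40 fell to 9 without control replicate 1, 12 without control replicate 2, 6 without control replicate 3 and 25 without YapCM-/- replicate 2. It was 27 without either other YapCM-/- replicate and 7 with the background subtracted. All 40 probes kept their sign in each of these fits.

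The proximal tubule list, the genes of the reabsorbing segment next to the glomerulus, gave the smallest p by camera at its preset correlation. With an estimated correlation and by fry, the ureteric bud tip list had the smallest p and not the proximal tubule list. Of the 9 tested proximal tubule members 3 fell and 6 did not pass over all probes, and 5 were lower adjusted over the list alone. Pdzk1, a scaffold for transporters of the brush border, fell by 1.02 (SE 0.140, adjusted p = 0.0313), with a control level 2.03-fold the mutant level, and Lrp2, the endocytic receptor megalin, fell by 0.91 (SE 0.131, adjusted p = 0.0344), from 9.05 ± 0.21 to 8.14 ± 0.21 (SD, n = 3 each). Keg1 fell by 0.84 (SE 0.132, adjusted p = 0.0465). Amn, the partner of cubilin, at -0.66 (adjusted p = 0.0935) and Slc34a1, the sodium-phosphate cotransporter, at -0.40 (adjusted p = 0.271) passed over the list alone, and both are named after their values were seen. The median difference of the list was -0.40, or -0.24 without control replicate 3, and camera of limma ranked it lower than other genes at an adjusted p of 1.56e-07. That call was lost, at adjusted p = 0.391, with an estimated correlation, and fry gave an adjusted p of 0.0677. Of the 6 fits that leave out 1 array, Pdzk1 missed the threshold in 4, Lrp2 in 5 and Keg1 in all 6.

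In the cap mesenchyme list, 2 of 22 tested members fell and 20 did not pass. Besides Meox2, Cited1, a transcriptional coregulator of the least committed progenitors, fell by 0.72 (SE 0.072, adjusted p = 0.00662), from 8.22 ± 0.02 to 7.50 ± 0.04 (SD, n = 3 each). Adjusted over the list alone, 7 members were lower and 1 higher. Six2, the transcription factor that maintains progenitors, stood at -0.36 (adjusted p = 0.193), Pax2 at -0.36 (adjusted p = 0.193) and Bmp7 at -0.31 (adjusted p = 0.20), with a dimmer probe at 0.10, among the lower ones, and Eya1 at 0.34 (adjusted p = 0.242) was the higher one; these 4 are named after their values were seen. The median of the list was -0.11, or -0.18 without control replicate 3, and camera placed it lower at an adjusted p of 0.00107. The call was lost, at adjusted p = 0.391, with an estimated correlation, and fry gave 0.0677. Cited1 missed the threshold without control replicate 3 (adjusted p = 0.0537) and Meox2 with the background subtracted (adjusted p = 0.0872).

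Genes of the early nephron, from the pretubular aggregate to the S-shaped body, went both ways. Of 21 tested members, Sox9, a transcription factor of ureteric bud tips and of early nephrons, rose by 0.52 (SE 0.078, adjusted p = 0.0422), from 11.34 ± 0.003 to 11.86 ± 0.09 (SD, n = 3 each), and 20 did not pass. Adjusted over the list alone, 5 were higher and 7 lower. The lower ones included Osr2 at -0.66 (adjusted p = 0.0870), Irx2 at -0.58 (adjusted p = 0.0943), Fgf8 at -0.55 (adjusted p = 0.118) and Lhx1 at -0.46 (adjusted p = 0.0943), and the higher ones Pax8 at 0.39 (adjusted p = 0.231), all named after their values were seen. The list as a whole had a median of -0.01, from -0.10 to 0.06 with 1 array left out, and was not called by camera (adjusted p = 0.275). The mixed test of fry, for changes in either direction, gave an adjusted p of 0.000676. Other probes of Lhx1 stood at 0.01 and of Pax8 at 0.12 and -0.03, and the dimmer probe of Sox9 at 0.37 (adjusted p = 0.224). Sox9 missed the threshold in all 6 fits that leave out an array.

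Podocyte genes were not called as a list (median -0.06, from -0.09 to -0.02 with 1 array left out, camera adjusted p = 0.184). The mixed test of fry gave an adjusted p of 0.00188. Of the 12 tested members 0 passed over all probes in limma, 3 were lower at an unadjusted p under 0.05, and the same number adjusted over the list alone. Nes, the intermediate filament nestin, was at -0.41 (adjusted p = 0.179) and Podxl, the podocyte surface protein podocalyxin, at -0.41 (adjusted p = 0.230). Among the 25% of probes with the highest mean the list was called lower, at a median of -0.33 (adjusted p = 0.038).

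The ureteric bud tip list was higher in YapCM-/- kidneys. Ret rose and the other 9 of its 10 tested members did not pass, and 4 were higher adjusted over the list alone: Ret, Ros1 at 0.36 (adjusted p = 0.128), Gfra1, the GDNF coreceptor, at 0.33 (adjusted p = 0.309), and Etv5, an ETS factor, at 0.30 (adjusted p = 0.239), the last 3 named after their values were seen. The median was 0.14, and camera gave an adjusted p of 0.00306. By camera with an estimated correlation the list stood at adjusted p = 0.391 (unadjusted p = 0.0227), and by fry at 0.0352. The estimated correlation of this list was -0.000127, below the preset 0.01. That argues against correlation among these genes as the source of the higher p. The few residual degrees of freedom of this variant raise p by themselves. In RNA of whole kidneys, a rise per cell and a larger share of tip cells cannot be told apart. Endothelium, which was not called, also had a median of 0.14. The FGF and GDNF signalling list, which shares members with the ureteric bud tip list, was not called (median 0.08, adjusted p = 0.0761). Of its 15 tested members Ret and Fgf10 rose. Adjusted over the list alone 4 were higher and 1 lower. It was called without control replicate 2 (adjusted p = 0.0365) and without YapCM-/- replicate 2 (adjusted p = 0.0236). Ureteric stalk and duct genes were not called (median 0.10, adjusted p = 0.275), with 0 of 12 members past the threshold in limma, over all probes or adjusted over the list alone, and 1 higher and 1 lower at an unadjusted p under 0.05; Cdh16 was at 0.39 (adjusted p = 0.230) and Cdh1, E-cadherin, at -0.20 (adjusted p = 0.427), with a dimmer probe at 0.02.

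Of the 15 tested members of the YAP/TEAD target signature 0 passed over all probes in limma, 5 were lower at an unadjusted p under 0.05, and 1 was lower adjusted over the list alone, Igfbp3 at -0.41 (SE 0.092, adjusted p = 0.161). Dock5 was at -0.25 (adjusted p = 0.314). Fjx1, named after its values were seen, was at -0.21 (adjusted p = 0.418) on its brightest probe and at -0.57 (adjusted p = 0.0897) on a dimmer one. The classical targets Ccn2, at -0.37 (adjusted p = 0.492), and Ccn1, at -0.24 (adjusted p = 0.336) with dimmer probes at -0.11 and 0.02, did not pass and are named after their values were seen. With a median of -0.09 the list was called lower by camera (adjusted p = 0.0235), a call lost at adjusted p = 0.391 with an estimated correlation, by fry (adjusted p = 0.162), with no filter on dim probes, with array weights and without any of control replicate 2, control replicate 3 and YapCM-/- replicate 1. Its median was -0.14 without control replicate 1 and -0.17 without YapCM-/- replicate 2. Of the 18 tested Hippo pathway components only Yap1 passed, over all probes and adjusted over the list alone. This list, which contains the deleted gene, had a median of -0.06 and an adjusted p of 0.0235, and stood at adjusted p = 0.391 with an estimated correlation. It was not called by fry (adjusted p = 0.0677), with the background subtracted (adjusted p = 0.0756), without control replicate 1 (adjusted p = 0.0829) or without YapCM-/- replicate 1 (adjusted p = 0.0713).

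Hypoxia and glycolysis genes were lower as a list, with a median of -0.18 over 13 tested members (camera adjusted p = 0.00141), a call lost at adjusted p = 0.449 with an estimated correlation. Of the members 0 passed over all probes in limma, and 4 were lower both at an unadjusted p under 0.05 and adjusted over the list alone. Aldoa, a glycolytic aldolase, was at -0.55 (SE 0.115, adjusted p = 0.128) and Ndrg1, a hypoxia-responsive gene, at -0.34 (SE 0.078, adjusted p = 0.171). Without control replicate 1 the median was -0.08 and the list was not called (adjusted p = 0.135). The median was -0.32 without control replicate 2 and -0.11 without YapCM-/- replicate 2. Control replicate 1 stood 0.24 above the control mean in the median of these genes, against -0.16 and -0.01 for the other control arrays.

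**Figure D2:**
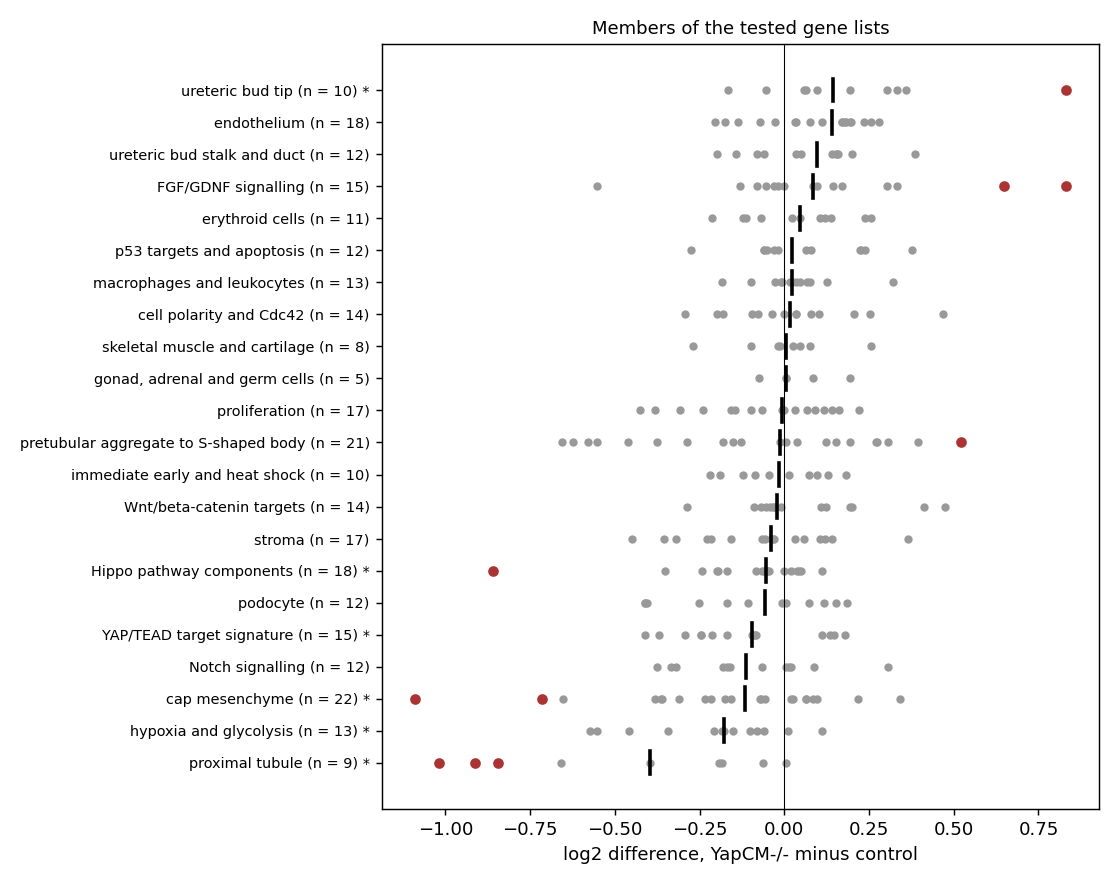
Log2 difference between YapCM-/- and control kidneys (horizontal axis) for each tested member of the 22 gene lists with a test (vertical axis, number of members in brackets), with members past the threshold over all probes in red, the others in grey, and the list median as a black bar; an asterisk marks lists called by camera with its preset correlation. The proximal tubule median lies at -0.40, the cap mesenchyme median at -0.11 and the ureteric bud tip median at 0.14.

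Other signalling and cell-state lists were not called by camera, which looks for a shift 1 way. The mixed test of fry, for changes in either direction, gave adjusted p from 0.000736 (Notch signalling) to 0.0338 (proliferation). Notch signalling had a median of -0.11 (camera adjusted p = 0.0930) over 12 tested members, with 1 higher and 3 lower adjusted over the list alone. Its target Nrarp was at -0.33 (adjusted p = 0.230) and the ligand Jag1 at -0.37 (adjusted p = 0.273). The Wnt/beta-catenin target list had a median of -0.02 while camera ranked it upward (adjusted p = 0.333), so that median and test differ in sign. Of its members, 2 of 14 members were higher and 1 lower adjusted over the list alone. The feedback inhibitor Notum was at 0.47 (adjusted p = 0.118) and Sp5 at 0.41 (adjusted p = 0.173). Proliferation genes had a median of -0.01 (adjusted p = 0.277), with 1 of 17 members lower adjusted over the list alone, Mcm7, a subunit of the replicative helicase, at -0.43 (adjusted p = 0.108). Rrm2 was at -0.31 (adjusted p = 0.319) on its brightest probe, with a probe of similar brightness at -0.0012 and a dim one at 0.08. The p53 target and apoptosis list had a median of 0.02 (adjusted p = 0.275), with Trp53inp1 at 0.38 (adjusted p = 0.292) and Mdm2 at 0.23 (adjusted p = 0.302) on its brightest probe, its other probes being at -0.14 and -0.0099. Cell polarity and Cdc42 genes had a median of 0.02 (adjusted p = 0.938), with Mpp5 at -0.29 (adjusted p = 0.230) and Rac1 at 0.25 (adjusted p = 0.271). Immediate early and heat shock genes had a median of -0.02 (adjusted p = 0.668), with Egr1 at -0.22 (adjusted p = 0.363) and Junb at -0.19 (adjusted p = 0.416). In all 6 lists of this paragraph 0 members passed over all probes in limma, and in the last 3 also 0 adjusted over the list alone. At an unadjusted p under 0.05, 4 p53 targets were higher, 2 polarity genes were higher and 2 lower, and 2 immediate early genes were lower. With 1 array left out, the median ran from -0.11 to 0.03 for proliferation genes and from -0.14 to -0.07 for Notch signalling. For Wnt/beta-catenin targets it ran from -0.03 to 0.07.

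Markers of the other cell types of the organ and of its neighbours gave no called list. Stroma had a median of -0.04 (camera adjusted p = 0.279), with 1 of 17 members lower adjusted over the list alone, Col1a1 at -0.35 (adjusted p = 0.193), and Pdgfrb at -0.32 (adjusted p = 0.273). Endothelium had a median of 0.14 (adjusted p = 0.108), with Esam at 0.28 (adjusted p = 0.283) and Tek at 0.20 (adjusted p = 0.381). Erythroid cells had a median of 0.04 (adjusted p = 0.379), with Slc4a1 at 0.26 (adjusted p = 0.397) and Hba-a1 at 0.24 (adjusted p = 0.462). Macrophages and leukocytes had a median of 0.02 (adjusted p = 0.612), with Laptm5 at 0.32 (adjusted p = 0.249) and Fcgr3 at -0.18 (adjusted p = 0.575). Gonad, adrenal and germ cell genes had a median of 0.01 (adjusted p = 0.702), with Pou5f1 at 0.19 (adjusted p = 0.525) and Dppa5a at -0.08 (adjusted p = 0.783). Skeletal muscle and cartilage genes had a median of 0.01, camera ranking them downward (adjusted p = 0.796), with Des at -0.27 (adjusted p = 0.246) and Col9a1 at 0.26 (adjusted p = 0.574). With 1 array left out, the median ran from -0.12 to 0.02 for stroma, from 0.06 to 0.18 for endothelium and from 0.03 to 0.13 for erythroid cells. Neurons and glia, with 4 tested members, and liver and gut, with 2, were too few for a list test. Elavl4 was at -0.29 (adjusted p = 0.223), Stmn2 at 0.45 (adjusted p = 0.474), Ttr at 0.64 (adjusted p = 0.494) and Trf at -0.01 (adjusted p = 0.982). Without YapCM-/- replicate 3, Stmn2 was at 0.16 and Ttr at 0.15. In these lists 0 members passed over all probes in limma, and adjusted over the list alone Col1a1 and Elavl4 were lower. At an unadjusted p under 0.05 stood 5 stromal and 5 endothelial genes, and 1 each of the erythroid, leukocyte, muscle and neural genes. The sex-linked genes were left out of the list tests. Uty was at 0.16 (adjusted p = 0.497) and Eif2s3y at 0.08 (adjusted p = 0.985), with dimmer probes at -0.02 and -0.01. Xist was high on 1 array of each group, control replicate 2 and YapCM-/- replicate 3.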

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

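The alternatives with the 25% of probes with the highest mean, background subtraction, cyclic loess and the Xist signal as a covariate were chosen after seeing the data. Against 40 probes, 38 passed with no filter, 41 with array weights, 38 after cyclic loess and 28 with a 1.5-fold minimum. The count was 64 with trend and robust options (35 shared), 67 with the Xist covariate (40 shared), 87 at an adjusted p of 0.10, 26 genes with the mean of each gene's probes (24 shared), 26 among the 25% of probes with the highest mean (14 higher, 12 lower, against 17 and 23), and 7 with the background subtracted. Leaving out 1 array gave 6 to 27 probes, with 20 higher and 7 lower without YapCM-/- replicate 1; each such fit has fewer samples. All 40 probes kept their sign in every probe-level fit that tested them. The labels do not say whether the same replicate numbers in both groups pair the arrays. Deviations of same-numbered arrays correlated at 0.13, 0.14 and -0.02, and not every array correlated best with its own number. These values leave a pairing open. With the replicate block 138 probes passed, including all 40, and it changed no list's call and, among the named genes, only that of Aldoa (-0.55, adjusted p = 0.0352 against 0.128).

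Yap1 ranged from -0.92 to -0.78 with an array left out (adjusted p 0.0191 to 0.0954) and was at -1.08 with the background subtracted (adjusted p = 0.178), where 7 of the 40 calls remained; subtraction raised the median size of the 40 differences from 0.70 to 1.05, and the cause of the lost calls was not tested. Subtracting a positive value from the signals enlarges their ratios by arithmetic, so the larger differences are no measure of the background in these data.

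With an estimated correlation the lists for YAP/TEAD targets (-0.0946), Hippo components (-0.0553), cap mesenchyme (-0.11), proximal tubule (-0.40) and ureteric bud tip (0.14) had adjusted p = 0.391, and hypoxia and glycolysis (-0.18) 0.449; the medians do not depend on the test. By fry the adjusted p was 0.162 for YAP/TEAD targets, 0.0677 for Hippo components, cap mesenchyme and proximal tubule, and 0.255 for hypoxia and glycolysis. YAP/TEAD targets were also not called with no filter (-0.0853, adjusted p = 0.056) or array weights (-0.0825, adjusted p = 0.0534), and ranged from -0.17 to -0.0718 with an array left out (adjusted p 0.00514 to 0.182). Hippo components were not called with the background subtracted (-0.11, adjusted p = 0.0756) and ranged from -0.0759 to -0.0395 with an array left out, not called without control replicate 1 (adjusted p = 0.0829) or YapCM-/- replicate 1 (adjusted p = 0.0713). Hypoxia and glycolysis ranged from -0.32 to -0.0819, and FGF/GDNF signalling from -0.0206 to 0.11, with an array left out. Podocyte genes were called among the 25% of probes with the highest mean (-0.33, adjusted p = 0.038). Few degrees of freedom alone raise p with an estimated correlation, so lost calls need not come from gene correlation. For ureteric bud tip the estimate, -0.000127 against the preset 0.01, argues against that source. Other changes had no tested cause. The cap mesenchyme (-0.18 to -0.11), proximal tubule (-0.51 to -0.24) and ureteric bud tip (0.14 to 0.20) lists kept their camera call, at its preset correlation, with each array left out. Spink1, Flrt1 and Slc32a1 passed in all 15 alternatives run for them.

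The alternatives that need the table of values before normalization (no background correction, median centring or cyclic loess after neqc, an offset of 50, a detection p of 0.01) and a slide block were not run, and the deposited value table, planned as an alternative, became the starting point.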

Other observations

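The tests in this part were chosen after the results were seen, except the count of called genes near Yap1, and the genes of the next paragraph were picked after their values were seen.

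Outside the lists, Car4, a membrane-bound carbonic anhydrase, fell by 0.54 (limma adjusted p = 0.0424). Some further genes did not pass and are given as values, without a test of what they have in common. Car14, another carbonic anhydrase, was at -0.42 (adjusted p = 0.0868), Anpep, the brush border aminopeptidase N, at -0.43 (adjusted p = 0.0870), and Fxyd2, the gamma subunit of the sodium pump, at -0.78 (adjusted p = 0.0943). Hdc, histidine decarboxylase, was at -0.83 (adjusted p = 0.0868).

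The real split of the 6 arrays gave 40 probes past the threshold and the highest of the other splits 3. Of the 10 splits, 1, the real one, gave as many, and 10 splits are too few for a share under 0.05.

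The median of the proximal tubule list was lower in each YapCM-/- array, at -0.40, -0.39 and -0.39 against the control mean, with control arrays at -0.08, -0.16 and 0.23. In the YapCM-/- arrays this median was the value of 1 gene, Slc34a1. It read 7.15 ± 0.007 (SD, n = 3) there, below the array median of 7.30. The closeness of the 3 YapCM-/- values is thus that of 1 dim probe, not of the list. The called members, chosen by their test, kept most of their fall with any array left out. Pdzk1 stayed at or below -0.86, Lrp2 at or below -0.80 and Keg1 at or below -0.67. With all arrays they were at -1.02, -0.91 and -0.84. A single control array with many tubules may account for part of the fall: the median without control replicate 3 was -0.24, which runs against it as the whole source, but the list was then called by camera at its preset correlation only (adjusted p = 2.22e-05, against 0.561 with an estimated correlation and 0.0574 by fry). A lower share of all nephron epithelium stays open too: with the background subtracted the mean was -1.06 for 9 proximal tubule and -0.11 for 12 podocyte genes (exact permutation p = 0.00251), but that test takes genes as independent and the estimated correlation within the proximal tubule list was 0.551. Less advanced kidneys would hold as many progenitors or more, and the cap mesenchyme values run against that, with all 3 YapCM-/- arrays below all control arrays, but the list's adjusted p reached 0.391 with an estimated correlation, and progenitors are the cells taken here to carry the deletion, so their genes are no independent measure of age. The genotype, the difference that the design names, stays open and was not tested apart from these.

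The fall of the hypoxia and glycolysis list may come in part from 1 control array under lower oxygen at collection. Without control replicate 1 the median was -0.08 and the camera adjusted p was 0.135. The adjusted p of the list over the 6 fits with an array left out ranged from 4.02e-07 to 0.135. Aldoa and Ndrg1, its members with the smallest p, did not rest on that array. With any array left out they stayed at or below -0.43 and -0.31. At most of the 13 tested members the groups overlapped. Less blood in the YapCM-/- samples is argued against. The erythroid list median of the lowest YapCM-/- array stood 0.012 above the control mean, where a loss of blood cells would have lowered it. That comparison looked only for less blood, so it says nothing against more blood in these samples. An effect of the genotype was not tested apart from these sources.

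Of 15 called genes with another tested probe that was not called, the brightest other probe had the same sign in 11 and the opposite sign in 4, Mff, Pigt, Col26a1 and 1700109H08Rik. Strain haplotypes that differ between the groups, on this mixed background, could change single probes. Of the 34 called genes with a place in the gene order, 9 lay within 100 protein-coding genes of another, and random draws gave a median of 9 (permutation p = 0.510). Sostdc1 and Meox2, which both fell, lay 2 genes apart, and Mff and Wdfy1 lay 11 apart. A window of 100 genes does not test for such close pairs. Haplotypes stay open, at single probes and at close pairs. Of the 59 other tested genes within 100 genes of Yap1, 0 were called. The called genes with a place in the gene order are thus not neighbours of the deleted gene. With 35 of 11762 tested genes called, few or none would be called among 59 in any case. The count therefore says nothing about smaller differences in these neighbours. Probe sequences were not analysed here.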
